A study of Mus musculus with 12 samples.

How the data were processed

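RNA from TT2 mouse embryonic stem cells was sequenced in 12 libraries that fell into 4 groups of 3. Wild-type cells (WT) and cells lacking both Rlf and Zfp292 (double knockout, DKO) were each sampled in ES medium with knockout serum replacement, FBS and LIF, which the series calls Serum/LIF (serum/LIF below), and after 72 hours without LIF in 5 µM retinoic acid (RA). Per the labels' protocols, total RNA was extracted with ISOGEN and libraries of 3 biological replicates were sequenced as paired-end reads. The labels do not say whether the replicates of a genotype came from separate clones, how the libraries were prepared, or whether they keep strand. Groups were taken from the sample titles and genotype labels.

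The submitters' processing notes name Trim Galore 0.6.10, STAR 2.7.11b, featureCounts from Subread 2.0.6, DESeq2 1.44.0 and the build mm10. The settings for reads that map to several places and for strand are not given in the sources used here. The authors deposited a table of 17901 genes and a table of 1387 repeat names. In both, the deposited library columns hold a signal: every value was a whole number of reads divided by a size factor of its library (100% of values within 0.01 of a whole read), and their mean over the 12 libraries was the mean normalized count that the authors' DESeq2 output lists. Per the file headers, the tables also hold the authors' log2 fold changes with their standard errors, a score (the Wald statistic) and p-values, raw and adjusted, for 4 comparisons. Of these, the adjusted p-values and signs were used, for a side-by-side count of calls. The repeat table carries size factors of its own.

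The values were transformed as log2(value + 1). Genes and repeats with a value of 10 or more in at least 3 libraries were kept, which left 15750 genes and 1170 repeats and put 2151 genes and 217 repeats below the filter. The counts were deposited as normalized values, so limma (limma 3.58.1 in R 4.3.3, empirical Bayes with trend and robust settings) was used and not a test for raw counts. All 12 libraries entered 1 fit with 1 mean per group and no replicate block. Contrasts were DKO against WT in serum/LIF, DKO against WT after RA, RA against serum/LIF in WT, RA against serum/LIF in DKO, and the interaction, which is the genotype effect after RA minus that in serum/LIF. A gene or repeat was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes given on the log2 scale carry the standard error (SE) of the limma fit, and folds without a scale are ratios of group means.

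Before the data were examined, 23 gene lists were fixed. They cover the CoREST complex, Polycomb and trithorax proteins, naive, general and formative pluripotency, the RA response, Hox genes, neural progenitors, neurons, neuronal targets of REST, endoderm, mesoderm, trophoblast, the two-cell-like state, germline, bivalent developmental regulators, fibroblasts, p53 response, stress, imprinted genes, Y-linked genes, proliferation and mitochondrially encoded genes. The last list had 0 genes in the table and was not analysed here. The bivalent list was written from general knowledge of developmental regulators, not from chromatin data of these cells, and it shares 14 genes with the neural progenitor list, 7 with the mesoderm list and 5 with the endoderm list. Lists were tested against all other tested genes with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison.

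The genes named in the text follow a rule fixed at the same time. It takes Rlf and Zfp292 and, for each comparison, the 5 higher and 5 lower genes with the largest fold change among called genes with a mean of 100 or more in the higher group and groups that do not overlap. For the interaction the mean was taken in the highest of the 4 groups, and no separation of groups was asked. It adds up to 4 called members of each list with the smallest adjusted p, or 1 member where none was called. A gene taken for 1 comparison is also given in others. Predicted genes were left out. Repeats were named from a list of families and, for each comparison, the 3 higher and 3 lower with the largest fold change. The text names part of this choice, and 1 gene within it is not reported here.

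Whole reads were recovered by multiplying the values by the size factors. They were used for depth, for counting intervals (95%, Poisson) and for folds against a group with 0 reads, where 3 counts over the group stood in for 0. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The recovered depth was 30869766 to 40236799 reads per library in genes and 2164824 to 3121854 in repeats.

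The test was run on simulated counts, drawn for all 12 libraries from the WT serum/LIF means with the real size factors and dispersions estimated by edgeR, with changes put into DKO in serum/LIF alone. On 14952 simulated genes it recovered 71.6%, 97.0% and 100% of 67, 67 and 66 genes changed by 1.5, 2 and 4 fold, with 16 false calls among 195. On 1162 simulated repeats it recovered 65%, 90% and 100%, with 1 false call among 52.

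Alternatives were a replicate block, TMM rescaling (edgeR 4.0.16), no filter, limma without trend, pseudocounts of 0.5 and 5, only the 6 libraries of a comparison, a log2 fold change of 1 or more, an estimated correlation for lists, and leaving out each library. Chosen after the data were seen were edgeR's quasi-likelihood test on the recovered reads, the gene table's size factors for the repeats, and gene lists without 1 library that was rich in rRNA-class repeats. For the repeats, scaling on their own table gave the same values as TMM rescaling. Overlaps of calls between both genotype effects were tested with Fisher's exact test, one-sided. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.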

Results

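The series asked how Rlf and Zfp292, which encode zinc finger proteins, act on gene expression in TT2 cells, a line of mouse embryonic stem cells, and its title names bivalent genes and the CoREST complex. Normalized counts for genes and for repeats were compared between WT and DKO cells, with 3 libraries per group. The libraries held 30869766 to 40236799 reads in genes. Normalized totals were 37250835 ± 332734 (SD, n = 3) in WT and 36809323 ± 145789 in DKO in serum/LIF, and 31091564 ± 103778 and 31290987 ± 69379 after RA. On the first principal component, which held 74.5% of the variance, and on the second, the replicates of each group lay together. One library stood apart. In the repeat table, rRNA-class repeats took 41.7% of the repeat reads in replicate 2 of WT after RA, against 4.14% to 7.28% in the other libraries. In the gene table it also differed more from its replicates, with a chi-square per degree of freedom of 10.5 and 14.9 against 5.19 between the other 2, and it lay at −24.7 on the third component, against −13.1 and −13.8. For every list below, the counts adjusted over the list alone were those given over all genes, except where others are named, and a list call held with an estimated correlation unless its p is given. SDs below are over 3 libraries, and a log2 fold change is followed by its SE with n = 3 libraries per group.

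Transcripts of both targeted genes were nearly absent from the libraries labelled DKO. Rlf (NM_001346660.1, mm10 chromosome 4, 121145883 to 121215084) had 3611 ± 96.3 normalized counts in WT in serum/LIF and 2611 ± 131 after RA. The DKO libraries held 6 Rlf reads in serum/LIF, 1571-fold fewer than WT (counting interval 722 to 4283), and 1 read after RA, 8530-fold fewer (1531 to 336955). Zfp292 (NM_013889.2, chromosome 4, 34803110 to 34882948) had 4909 ± 324 normalized counts in WT in serum/LIF and 3166 ± 363 after RA, and 0 reads in the DKO libraries of either condition, which made it at least 4276-fold lower in serum/LIF and at least 3454-fold lower after RA.

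**Figure D1:**
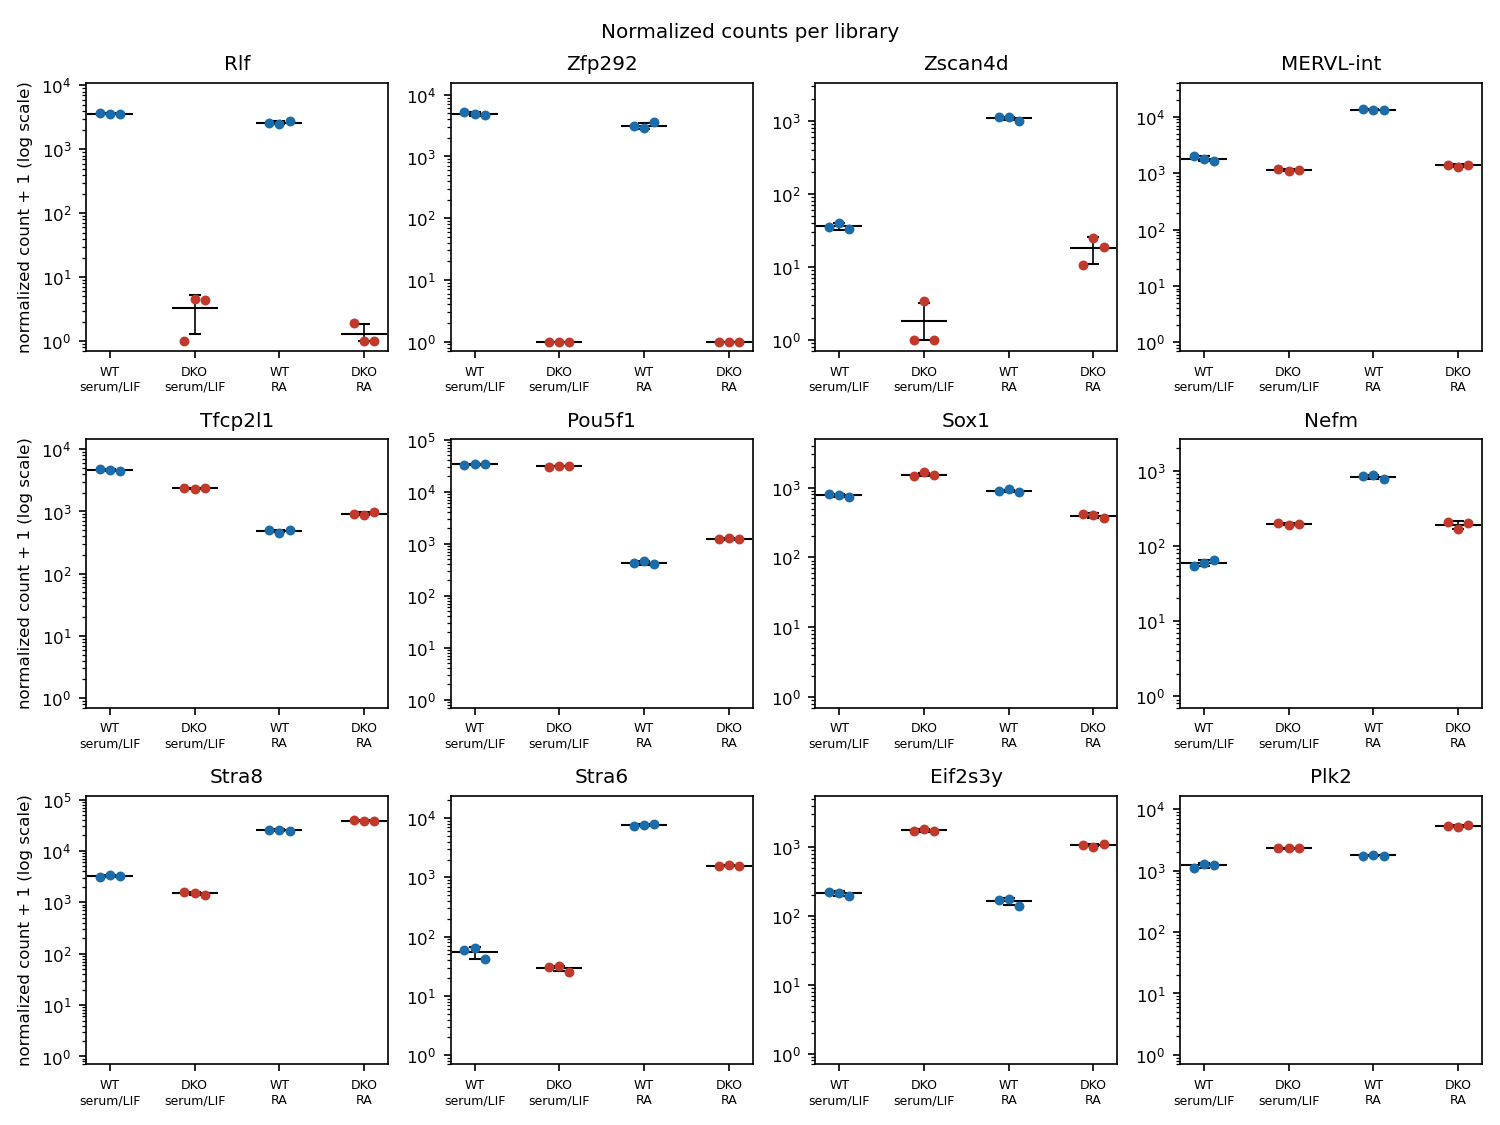
Normalized counts plus 1 on a log scale (y axis) for 11 genes and the repeat MERVL-int in each of the 4 groups (x axis). Points are the 3 libraries of a group, the horizontal bar is the mean and the whiskers are 1 SD; Zfp292 lies at 0 reads in all 6 DKO libraries, and the MERVL-int mean of 13281 in WT after RA stands above the DKO mean of 1369.

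In serum/LIF, two-cell-like and naive pluripotency genes were lower in DKO and genes of several differentiated lineages higher. The Zscan4 genes, which mark the two-cell-like state of a few embryonic stem cells, fell to a few reads. Among fibroblast markers, Acta2 was at 4.26 times and Col3a1 at 6.16 times the WT mean. The neural progenitor genes Sox1 and Fabp7 were at 1.99 and 4.35 times their WT means, and the Y-linked Eif2s3y, a translation factor gene, was at 8.28 times its WT mean. In all, 5230 of 15750 genes were called, 2801 higher and 2429 lower in DKO.

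Beyond Rlf and Zfp292, the genes with the largest decreases were Vwa3b (log2 fold change −4.95 ± 0.51), Nlrp4a (−4.88 ± 0.39), a member of the NLR family, and Oas1g (−3.88 ± 0.50), an oligoadenylate synthetase of the interferon response. The largest increases were in Tex13b (6.40 ± 0.21), Usp9y, Npy (4.25 ± 0.73), which encodes neuropeptide Y, the protocadherin Pcdh17 (3.28 ± 0.32) and Eif2s3y (3.05 ± 0.10). Usp9y had 2 reads in WT and 318 in DKO, a ratio of 186 with a counting interval of 50.9 to 1538.

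Of 22 two-cell-like genes tested, 14 were lower, 1 was higher and 7 were not called, with a median log2 fold change of −2.46 (camera adjusted p = 1.42e-07). Adjusted over the list alone, 18 were lower and 1 higher. In DKO, 9 of these genes had 0 reads, and with those at their bound the median was −2.44. Zscan4d had 105 reads in WT and 2 in DKO, 45.0-fold fewer (12.2 to 376), Zscan4a was 54.9-fold lower (14.9 to 458), and Zscan4b, with 0 reads in DKO, was at least 15.7-fold lower. These copies are nearly identical, so the split of reads between them is uncertain.

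Naive pluripotency genes were lower, 10 of 18 with 1 higher and 7 not called, and 11 lower and 1 higher adjusted over the list alone (median −0.29, camera adjusted p = 0.000657). Tfcp2l1 (−0.98 ± 0.06), a transcription factor of the naive state, Tet2 (−0.84 ± 0.06), a 5-methylcytosine dioxygenase, and Socs3 (−0.46 ± 0.04), a feedback inhibitor of LIF signalling, fell, while Tbx3 (0.84 ± 0.07) rose. Formative and primed genes went the other way, with 10 of 18 higher and 4 lower, the same numbers adjusted over the list alone (median 0.30, camera adjusted p = 0.0263; adjusted p = 0.0587 with an estimated correlation). Cdh2 (1.19 ± 0.06), which encodes N-cadherin, rose, and the DNA methyltransferase gene Dnmt3a (−0.45 ± 0.04) fell. Of 14 general pluripotency genes, 2 were higher and 3 lower (camera adjusted p = 0.793).

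Fibroblast markers were higher in DKO in 12 of 17 cases and lower in 1, or 12 and 2 adjusted over the list alone (median 0.71, camera adjusted p = 1.06e-07). Acta2 (2.09 ± 0.04), Tagln (1.97 ± 0.04), Col1a2 (1.45 ± 0.04) and Col3a1 (2.63 ± 0.08) rose. This rise of markers of another cell type stood beside that of other lineage lists. Whether all cells or a share of the culture gave these rises was not tested. Trophoblast genes were higher in 9 of 17 cases and lower in 0 (median 0.66, camera adjusted p = 0.000155; adjusted p = 0.0539 with an estimated correlation), among them the keratins Krt8 (2.01 ± 0.08) and Krt18 (1.65 ± 0.07) and the homeobox gene Esx1 (1.87 ± 0.10). Endoderm genes were higher in 11 of 25 cases and lower in 3 (12 and 3 adjusted over the list alone, median 0.38, camera adjusted p = 0.00122), with the collagen IV genes Col4a2 (1.35 ± 0.05) and Col4a1 (1.12 ± 0.04). Mesoderm genes were higher in 9 of 20 cases and lower in 2, or 9 and 3 adjusted over the list alone (median 0.67, camera adjusted p = 0.0349; adjusted p = 0.183 with an estimated correlation). Kdr (2.21 ± 0.24), a VEGF receptor gene, rose, and Meox1 (−2.82 ± 0.29) fell.

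Neural progenitor genes were higher in 9 of 23 cases and lower in 2, or 12 and 3 adjusted over the list alone (median 0.40, camera adjusted p = 0.00788). Nes (0.76 ± 0.04), the intermediate filament gene nestin, Sox1 (0.99 ± 0.08) and Fabp7 (2.09 ± 0.26) rose, and Pax6 (−0.95 ± 0.12) fell. Neuronal targets of REST, the repressor that recruits CoREST, were higher in 7 of 24 cases and lower in 0 (median 0.23, camera adjusted p = 0.0154; adjusted p = 0.261 with an estimated correlation), with Vgf (2.30 ± 0.10) and Bex1 (0.41 ± 0.05) among them. The neuron list had 7 higher and 4 lower of 19 (camera adjusted p = 0.395). Hox genes were lower in 8 of 32 cases and higher in 1, or 6 and 1 adjusted over the list alone (median −0.31, and −0.25 with 1 gene at its bound, camera adjusted p = 0.039; adjusted p = 0.0741 with an estimated correlation), among them Hoxb2 (−0.89 ± 0.12) and Hoxa3 (−1.18 ± 0.18).

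Bivalent developmental regulators had 21 higher, 8 lower and 42 not called of 71, and 25 higher and 9 lower adjusted over the list alone, with a median of 0.44 that did not pass the list test (camera adjusted p = 0.0818). Sox1 was among the higher ones, and the signalling gene Bmp4 (−1.49 ± 0.14) and the homeobox gene Gbx2 (−0.71 ± 0.07) among the lower. The CoREST complex list had 1 higher, 5 lower and 9 not called of 15, or 2 higher and 5 lower adjusted over the list alone (median −0.07, camera adjusted p = 0.197). Kdm1a, which encodes the histone demethylase LSD1, was at −0.12 ± 0.04 (adjusted p = 0.016) and Rcor1, which encodes CoREST itself, at −0.15 ± 0.05 (adjusted p = 0.0217). Without replicate 2 of WT in serum/LIF neither was called (adjusted p = 0.0976 and 0.0739), nor was Rcor1 without replicate 3 of DKO in serum/LIF (adjusted p = 0.1). Over 20 alternatives the adjusted p ran from 0.0124 to 0.0976 for Kdm1a and from 0.0171 to 0.1 for Rcor1. Polycomb and trithorax genes went both ways, with 7 higher and 8 lower of 38 (camera adjusted p = 0.99), and Jarid2 (−0.43 ± 0.03) and Cbx7 (−0.31 ± 0.04) fell.

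Genes of the p53 response were higher in 8 of 16 cases and lower in 0 (median 0.15, camera adjusted p = 0.0011), among them Plk2 (0.94 ± 0.05), Ccng1 (0.37 ± 0.04) and Mdm2 (0.33 ± 0.04), the ligase gene that restrains p53. Imprinted genes were higher in 10 of 22 cases and lower in 5 (median 0.17, camera adjusted p = 0.0134), with Peg10 at 2.71 times its WT mean and Plagl1 at 1.31 ± 0.06. Y-linked genes were higher in 6 of 7 cases (median 1.37, camera adjusted p = 6.78e-06), with Ddx3y (1.40 ± 0.07) and Uba1y (1.37 ± 0.22) beside Eif2s3y. Proliferation genes were lower in 9 of 18 cases, or 11 adjusted over the list alone, and higher in 0 (median −0.10, camera adjusted p = 0.000349), with Top2a at −0.30 ± 0.03. The RA response list (7 higher and 8 lower of 18, camera adjusted p = 0.384), germline genes (10 and 4 of 24, 0.214) and stress genes (6 and 5 of 18, 0.918) did not pass. Adjusted over the list alone, germline genes had 12 higher and 4 lower and stress genes 6 and 7. The median and the mean of the RA response list differed in sign (0.16 and −0.06). So did those of the stress list (−0.02 and 0.13), and the Polycomb list had a median of 0.02 and a test direction of lower.

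After RA the same genotype difference took another shape. Pluripotency genes were higher in DKO, with Pou5f1 at 2.88 times and Dppa3 at 4.13 times the WT mean. Neural genes were lower, with Nefm 4.40-fold and Dbx1 14.4-fold lower. Two-cell-like genes were lower in this condition too, with Zscan4d 62.6-fold lower. In this comparison 6727 of 15750 genes were called, 3468 higher and 3259 lower, and with a log2 fold change of 1 or more 492 higher and 801 lower.

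**Figure D2:**
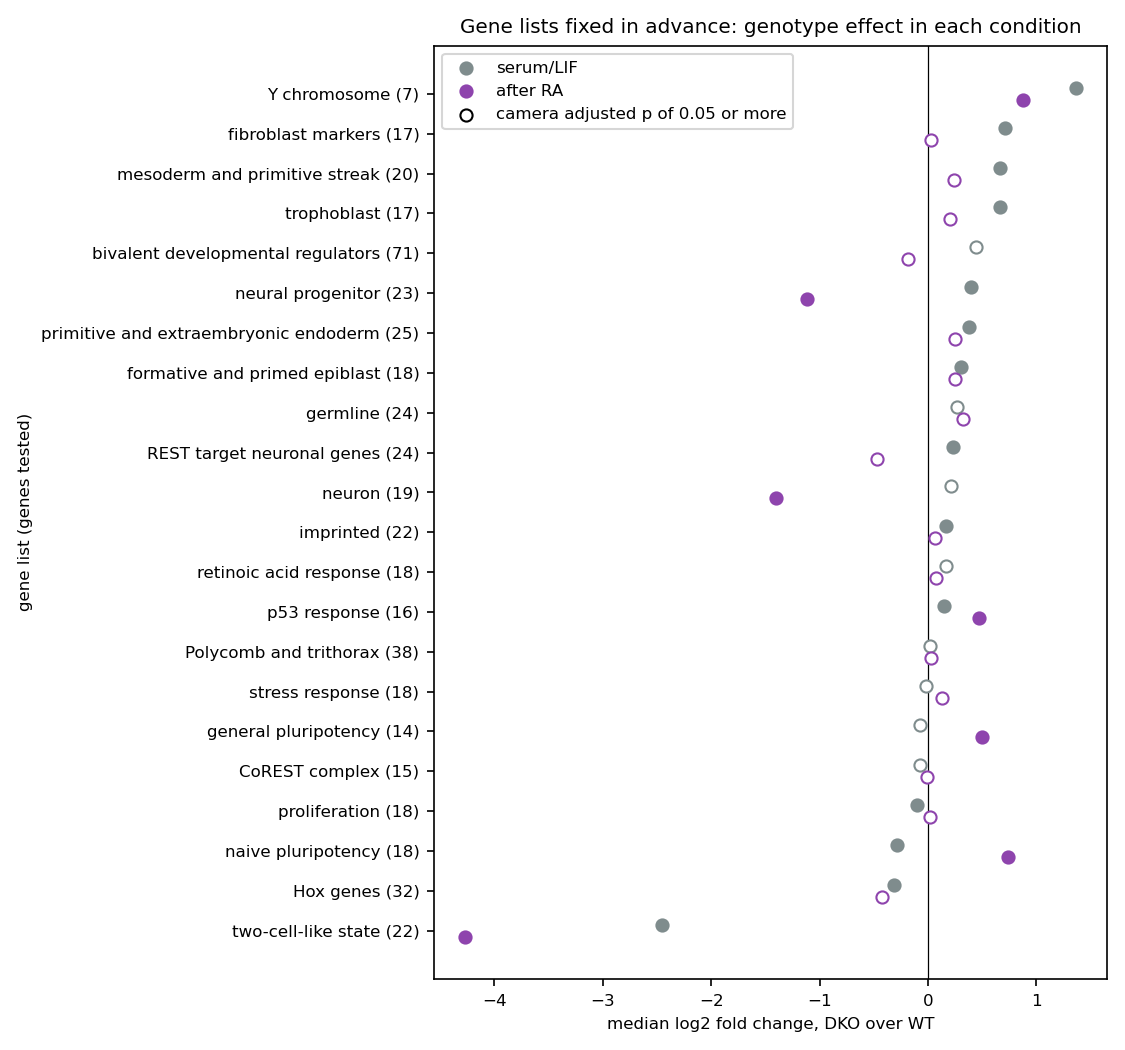
Median log2 fold change of DKO over WT (x axis) for each gene list with its number of genes tested (y axis), in serum/LIF (grey) and after RA (purple). Filled points passed camera at the preset correlation, open points did not; the two-cell-like list has medians of −2.46 and −4.27, and the neural progenitor list lies at 0.40 in serum/LIF and at −1.12 after RA.

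The genes with the largest increases after RA were Capn11 (3.48 ± 0.26), a calpain gene, Grin2c (3.47 ± 0.35), which encodes a glutamate receptor subunit, Usp26 (3.42 ± 0.10), a deubiquitinase gene, Cyp1a1 (3.42 ± 0.26), a cytochrome P450 gene, and Xist (3.02 ± 0.26), the RNA of X inactivation. Beyond both targets, the largest decreases were in Pramel39 (−6.33 ± 0.70), Zscan4d (−5.97 ± 0.42) and Zscan4a (−5.89 ± 0.45). Two-cell-like genes were lower in 20 of 22 cases and higher in 2 (median −4.27, camera adjusted p = 9.36e-10). Their levels in WT had risen with RA, and Zscan4d stood at 1069 ± 61.4 normalized counts in WT and 17.1 ± 7.23 in DKO.

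Naive pluripotency genes were higher in DKO in 12 of 18 cases and lower in 3, or 14 and 3 adjusted over the list alone (median 0.74, camera adjusted p = 1.06e-05). General pluripotency genes were higher in 12 of 14 and lower in 1 (median 0.50, camera adjusted p = 5.32e-08). Pou5f1 (1.52 ± 0.05), which encodes OCT4, Utf1 (1.62 ± 0.07), Nanog (1.41 ± 0.07), Klf2 (1.12 ± 0.05), Dppa3 (2.03 ± 0.11) and Tfcp2l1 (0.93 ± 0.06) were higher. Their levels were small beside those of undifferentiated cells, with Pou5f1 at 428 ± 34.4 in WT and 1230 ± 35.7 in DKO after RA and at 33444 ± 730.3 in WT in serum/LIF.

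Neural progenitor genes were lower in 15 of 23 cases and higher in 4 (median −1.12, camera adjusted p = 0.000101). Neuron genes were lower in 16 of 19 and higher in 1 (median −1.40, camera adjusted p = 3.54e-07). Sox1 (−1.18 ± 0.08), Sox21 (−1.68 ± 0.13), Dbx1 (−3.85 ± 0.31) and Pax6 (−1.12 ± 0.12), all transcription factors of neural development, fell, as did Fabp7 (−3.09 ± 0.26). Among neuron genes the neurofilament genes Nefm (−2.13 ± 0.13) and Nefl (−1.56 ± 0.10), Ina (−1.11 ± 0.06) and the tubulin gene Tubb3 (−1.09 ± 0.07) fell. Nes (0.39 ± 0.04) remained higher. Neuronal targets of REST had 10 lower and 4 higher of 24, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.119), and Rest itself was higher (0.30 ± 0.06).

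Genes of the p53 response were higher in 14 of 16 cases and lower in 0 (median 0.47, camera adjusted p = 9.36e-10), with Plk2 (1.59 ± 0.05), Zmat3 (0.65 ± 0.05), Ccng1 (0.61 ± 0.04), Mdm2 (0.56 ± 0.04) and Bbc3 (0.76 ± 0.07), which encodes the death-promoting protein PUMA. Y-linked genes were higher in 6 of 7 cases (median 0.88, camera adjusted p = 0.000148), with Eif2s3y at 2.71 ± 0.10. The lists of other lineages did not pass, namely fibroblast (7 higher and 3 lower of 17, adjusted p = 0.424), trophoblast (6 and 2 of 17, 0.152), endoderm (9 and 5 of 25, 0.289), mesoderm (8 and 2 of 20, 0.16) and germline genes (9 and 4 of 24, 0.119). Adjusted over the list alone, fibroblast markers had 7 higher and 4 lower and germline genes 11 and 4.

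The RA response list had 5 higher and 6 lower of 18 (camera adjusted p = 0.963). Stra8 (0.61 ± 0.04), a meiosis gene that RA induces, the receptor gene Rarg (1.22 ± 0.04) and the binding protein gene Crabp2 (0.37 ± 0.05) were higher, while the retinol transporter gene Stra6 (−2.28 ± 0.13), Crabp1 (−2.66 ± 0.10) and Meis1 (−0.37 ± 0.08) were lower. Hox genes had 1 higher, 8 lower and 23 not called of 32, or 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0985), with Hoxb8 (−0.90 ± 0.15) and Hoxd3 (−1.96 ± 0.37) lower. Imprinted genes moved both ways, 7 higher and 9 lower of 22 (camera adjusted p = 0.31), with Dlk1 (−3.68 ± 0.11), Igf2 (−1.43 ± 0.05) and Igf2r (−1.46 ± 0.04) lower and Peg10 (0.35 ± 0.05) higher. Bivalent regulators had 13 higher and 20 lower of 71 (median −0.19, camera adjusted p = 0.119), with Gbx2 (−1.29 ± 0.07) and Sox3 (−1.86 ± 0.12) lower. The CoREST list had 3 higher and 3 lower of 15 (camera adjusted p = 0.933), with Gse1 (0.47 ± 0.04) higher. Polycomb and trithorax genes had 13 higher and 3 lower of 38, or 14 and 3 adjusted over the list alone (camera adjusted p = 0.268), with Jarid2 (0.37 ± 0.03) higher and Cbx7 (−1.30 ± 0.04) lower. Formative genes had 7 higher and 5 lower of 18, or 7 and 6 adjusted over the list alone (0.268), with Etv5 (1.53 ± 0.06) higher. Stress genes had 6 and 5 of 18 (0.835), and proliferation genes 3 and 4 of 18 (0.994). Medians and means differed in sign for the RA response (0.07 and −0.15), imprinted (0.06 and −0.34) and fibroblast lists (0.02 and −0.09). Without replicate 2 of WT after RA the RA response median was 0.02 (camera adjusted p = 0.966) and the fibroblast median 0.16 (0.324). The CoREST list had a median of −0.01 and a mean of 0.03, and the proliferation list a median of 0.02 and a mean of −0.000349.

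RA itself changed most of the transcriptome. In WT it silenced pluripotency genes and induced Hox genes, direct RA targets, endoderm genes and fibroblast markers, with Cyp26a1, which encodes the enzyme that clears RA, at 273 times and Hoxb8 at 586 times their serum/LIF means and Pou5f1 78.2-fold lower. In DKO the same lists moved the same way, with Cyp26a1 at 359 times, Hoxb8 at 236 times and Pou5f1 25.1-fold lower. In WT 12695 of 15750 genes were called, 6515 higher and 6180 lower. In DKO 12340 were, 6326 higher and 6014 lower. Across genes, which are not independent replicates, the fold changes of both genotypes correlated at r = 0.89, with a slope of 0.75 of DKO on WT.

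Naive pluripotency genes fell in 16 of 18 cases in WT and 17 of 18 in DKO (medians −4.73 and −3.71, camera adjusted p = 9.76e-08 and 2e-08). All 14 general pluripotency genes fell in both (medians −3.43 and −2.96, camera adjusted p = 4.8e-10 and 2.3e-10). In WT, Zfp42 fell by 4.69 ± 0.05 and Esrrb by 6.17 ± 0.07 on the log2 scale. Formative genes fell in 13 of 18 cases in WT and 14 in DKO (medians −3.38 and −3.35, camera adjusted p = 0.0028 and 0.000496). The largest decreases in WT were in Otx2 (−8.84 ± 0.47), a transcription factor of the primed state, Tdh (−8.21 ± 0.09), which encodes threonine dehydrogenase, Chrna9, Pirt and Tcl1 (−7.68 ± 0.72). Chrna9 was 580-fold lower with 2 reads after RA (160 to 4794), and Pirt, with 0 reads after RA, was at least 239-fold lower. In DKO the largest were in Vrtn (−8.49 ± 0.56), Tdh (−6.91 ± 0.09), Foxd3 (−6.66 ± 0.27) and Otx2 (−6.39 ± 0.47).

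Hox genes rose in 28 of 32 cases in WT and 29 in DKO (medians 6.28 and 6.50, camera adjusted p = 3.58e-09 and 2.66e-10). Hoxc5 (9.51 ± 0.83 and 10.22 ± 0.83), Hoxb5 (9.49 ± 0.42 and 9.67 ± 0.42) and Hoxc8 (9.20 ± 0.68 and 8.60 ± 0.68) were among the largest increases in WT and DKO, with Cyp26b1 (9.87 ± 0.36 and 9.32 ± 0.36), and in DKO Hoxb6 (9.86 ± 0.60) and Hoxc4 (9.26 ± 0.44) were too. Hoxd3, with 0 reads in serum/LIF, was at least 772-fold higher in WT and at least 171-fold higher in DKO. The RA response list rose in 17 of 18 cases in both (medians 3.94 and 4.27, camera adjusted p = 4.63e-08 and 7e-09), with Rarg as the member that fell (−2.52 ± 0.04 in WT and −0.90 ± 0.04 in DKO). Endoderm genes rose in 20 of 25 cases in both (medians 2.00 and 1.98, camera adjusted p = 1.95e-05 and 1.34e-05). Fibroblast markers rose in 15 of 17 in both (2.72 and 1.58, 2.43e-06 and 1.34e-05), imprinted genes in 18 of 22 and 17 (1.46 and 1.36, 3.36e-05 and 0.000428), and bivalent regulators in 53 of 71 and 47 (2.60 and 1.71, or 1.72 with 3 genes at their bound, 1.95e-05 and 0.000434). Col1a1 (3.12 ± 0.05), the keratin gene Krt19 (5.81 ± 0.08) and Kdm6b (1.99 ± 0.05), which encodes a demethylase of H3K27, rose in WT, and Phc1 (−2.40 ± 0.04), a Polycomb gene, fell. Proliferation genes fell in 15 of 18 cases in both (medians −0.66 and −0.59, camera adjusted p = 5.71e-05 and 0.000288).

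Several lists passed in one genotype. Neural progenitor genes rose in 17 of 23 cases in WT (median 3.02, camera adjusted p = 0.0011) and in 12 in DKO (1.07, 0.16). Two-cell-like genes rose in 20 of 22 in WT (3.88, 0.00554) and in 14 in DKO (2.13, or 1.95 with 8 genes at their bound, 0.0844). In DKO alone, p53 genes (12 higher and 2 lower of 16, 0.000521, against 0.0541 in WT) and trophoblast genes (9 and 2 of 17, 0.0191; adjusted p = 0.203 with an estimated correlation; 0.0521 in WT) passed. Without replicate 2 of WT after RA, the WT values were 0.0395 for p53 and 0.0456 for trophoblast genes, both passing. Adjusted over the list alone, trophoblast genes had 9 higher and 6 lower in WT and p53 genes 13 and 2 in DKO. The interaction tests these differences. The neuron list (11 higher and 5 lower of 19 in WT, 4 and 11 in DKO, adjusted p = 0.389 and 0.105), neuronal targets of REST (11 and 9 of 24, 7 and 11, 0.631 and 0.489), mesoderm (10 and 9 of 20, 9 and 10, 0.575 and 0.513), germline (12 and 10 of 24, 10 and 10, 0.901 and 0.825), CoREST (8 and 7 of 15 in both, 0.901 and 0.733), Polycomb and trithorax (14 and 22 of 38, 13 and 21, 0.0909 and 0.12), stress (10 and 7 of 18, 8 and 7, 0.977 and 0.922) and Y-linked genes (3 and 3 of 7, 1 and 4, 0.871 and 0.253) did not pass. Mesoderm genes had medians of −0.04 and −0.30 and means of 1.26 and 1.18, and germline genes a median of 0.38 and a mean of −0.31 in WT. The stress list in DKO had a median of 0.14 and a test direction of lower. Adjusted over the list alone, stress genes had 10 higher and 8 lower in WT and targets of REST 6 and 10 in DKO.

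The response to RA differed between genotypes in 4852 genes by the interaction test, 2328 with a larger log2 fold change of DKO over WT after RA than in serum/LIF and 2524 with a smaller one. Pluripotency genes were silenced less far in DKO, and neural genes were induced less or fell. Naive genes had 13 of 18 with a positive interaction and 2 with a negative one (median 1.30, camera adjusted p = 1.16e-08), and neural progenitor genes 2 and 16 of 23 (median −1.50, camera adjusted p = 7.82e-08). Among the largest positive interactions were those of Nlrp4a (4.10 ± 0.55), Accsl (3.61 ± 0.58), Slc15a1 (3.33 ± 0.46), a peptide transporter gene, and Myo1g (3.29 ± 0.71), and among the largest negative ones were Fabp7 (−5.18 ± 0.37), Dbx1 (−4.51 ± 0.44), Tex13b (−4.48 ± 0.30) and Vit (−4.46 ± 0.77).

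General pluripotency (11 positive and 1 negative of 14, median 0.50, camera adjusted p = 1.26e-07) and p53 genes (11 and 1 of 16, 0.30, 9.42e-06) had positive interactions. Negative ones were found for neuron (1 and 14 of 19, −1.60, 7.82e-08), fibroblast (1 and 12 of 17, −1.08, 3.93e-08), imprinted (3 and 12 of 22, −0.47, 3.12e-05) and bivalent genes (6 and 22 of 71, −0.58, 0.0016). The bivalent list shares 14 genes with the neural progenitor list and was not tested without them. Proliferation genes (7 and 0 of 18, 0.13, 0.00851; adjusted p = 0.123 with an estimated correlation), neuronal targets of REST (1 and 12 of 24, −0.80, 0.000641; adjusted p = 0.152 with an estimated correlation), trophoblast (4 and 7 of 17, −0.51, 0.0324; adjusted p = 0.264 with an estimated correlation) and two-cell-like genes (1 and 6 of 22, −1.31, 0.0189; adjusted p = 0.0916 with an estimated correlation) passed at the preset correlation. Without replicate 2 of WT after RA the adjusted p was 0.0501 for trophoblast and 0.0946 for two-cell-like genes. Over 3 alternatives it ran from 0.0309 to 0.264 and from 0.0151 to 0.0946. Without that library the median for neuronal targets of REST was −0.52 (adjusted p = 0.0043, over 3 alternatives 0.000535 to 0.152) and that for two-cell-like genes −1.11. In serum/LIF 9 of the 22 two-cell-like genes had 0 reads in DKO, which limits their genotype effect there. The size of this interaction therefore depends on the 1 added before the log2 step. Summed over 5 Zscan4 copies, the log2 genotype effect was −4.57 (SE 0.29) in serum/LIF and −5.52 (SE 0.06) after RA. Adjusted over the list alone, the positive and negative counts were 2 and 17 for neural progenitor genes, 1 and 13 for targets of REST, 4 and 8 for trophoblast and 6 and 24 for bivalent genes. They were 12 and 1 for p53, 4 and 12 for imprinted, 4 and 1 for CoREST and 9 and 6 for Polycomb and trithorax genes. For the others they were 6 and 6 for formative, 7 and 8 for RA response, 7 and 4 for germline and 1 and 3 for Y-linked genes. The CoREST (3 and 1 of 15, 0.308), Polycomb and trithorax (8 and 6 of 38, 0.438), formative (5 and 6 of 18, 0.604), RA response (6 and 7 of 18, 0.97), Hox (4 and 4 of 32, 0.926), endoderm (2 and 5 of 25, 0.0858), mesoderm (3 and 3 of 20, 0.926), germline (6 and 4 of 24, 0.439), stress (3 and 3 of 18, 0.926) and Y-linked lists (1 and 2 of 7, 0.308) did not. Medians and means differed in sign for Hox (0.11 and −0.03), mesoderm (0.02 and −0.08) and stress genes (0.02 and −0.03), and the RA response list had a median of −0.12 and a test direction of higher.

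Both genotype effects shared part of their genes. Among genes called in both conditions, 1176 were higher in both, against 617 from independent lists of the same sizes (Fisher's exact test, one-sided, p = 2.3e-155), and 1070 were lower in both, against 503 (p = 2.53e-181). This test takes genes as independent, so its p-values do not measure the spread between cultures. A further 347 genes were higher in serum/LIF and lower after RA, against 580 from independent lists, and 323 the reverse, against 535. With a log2 fold change of 1 or more, 100 were higher and 276 lower in both. Genes higher in DKO in serum/LIF overlapped those that RA raised in WT in 2015 cases, against 1159 from independent lists, and genes lower in DKO overlapped those that RA lowered in 1436, against 953. Both comparisons used the same WT serum/LIF libraries. In simulated unchanged groups against those controls, where 0.35 genes were called on average, ranked lists of the same sizes shared 1992 and 1729 genes. The covariance of the fold changes was 0.36 across genes, against 0.04 in the simulations, a difference of 0.32, and the correlation was 0.32 against 0.50. The 3 controls do not allow a split with at least 2 libraries on each side. The simulated groups held no real effects, so lists ranked in them held noise alone. Their shared counts and correlation cannot decide how much of the excess came from the shared libraries. The covariance, which keeps the size of the changes, lay above its simulated value. This argues against the shared libraries as its whole source, and part of the excess may still come from them. With a log2 fold change of 1 or more, 502 genes were higher in DKO and raised by RA, against 146 from independent lists. A further 230 were lower in both, against 91.7. In opposite directions, 35 were higher in DKO and lowered by RA, against 107, and 143 the reverse, against 125.

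Among repeats, MERVL, the endogenous retrovirus of the two-cell-like state, was lower in DKO. MERVL-int stood at 1819 ± 188 in WT and 1137 ± 50.9 in DKO in serum/LIF, and at 13281 ± 205 and 1369 ± 63.6 after RA, where it was 9.70-fold lower. Its long terminal repeat MT2_Mm fell by 0.46 ± 0.07 on the log2 scale in serum/LIF and by 2.29 ± 0.07 after RA. IAPEz-int (0.52 ± 0.05 and 0.78 ± 0.05), L1Md_T (0.34 ± 0.04 and 0.84 ± 0.04), L1Md_Gf (0.65 ± 0.12 and 0.98 ± 0.12), MMERGLN-int (0.30 ± 0.04 and 0.66 ± 0.04) and ETnERV3-int (0.95 ± 0.08 and 0.68 ± 0.08) were higher in DKO in both conditions. So were ETnERV-int, L1Md_A and L1Md_F2, but other listed members of these families did not all follow. RLTR1B, listed with MMERGLN-int, was lower in serum/LIF (−0.38 ± 0.10) and not called after RA. IAPLTR1_Mm, IAPLTR1a_Mm, ETnERV2-int and RLTRETN_Mm were called in neither condition. Of other listed retroviruses, RLTR9E (−0.42 ± 0.06 and −0.26 ± 0.06) and RLTR45-int (−0.54 ± 0.09 and −0.29 ± 0.09) were lower in both. In serum/LIF 115 of 1170 repeats were called, 65 higher and 50 lower, and after RA 129, 64 higher and 65 lower. The serum/LIF count was 72 to 117 when 1 library was left out, lowest without replicate 2 of WT in serum/LIF, and 61 with limma without trend.

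In serum/LIF the repeats with the largest increases were L1M6B (1.53 ± 0.16), the simple repeat (ATAAG)n (1.40 ± 0.05) and RLTR1B-int (1.02 ± 0.04), and RLTR16B_MM (−1.24 ± 0.12) and RLTR51B_Mm (−1.10 ± 0.18) fell. After RA, IAPLTR3-int (1.41 ± 0.18), Ricksha_c (0.99 ± 0.11) and IAPLTR2_Mm (0.99 ± 0.14) were higher, and the major satellite GSAT_MM (−1.74 ± 0.22), the VL30 element MMVL30-int (−0.87 ± 0.05) and its long terminal repeat RLTR6_Mm (−1.08 ± 0.11) were lower. RA raised MMVL30-int (3.63 ± 0.05 in WT and 2.60 ± 0.05 in DKO), (ATAAG)n (4.48 ± 0.05 and 3.25 ± 0.05) and ERVB4_1-I_MM-int (4.39 ± 0.19 and 4.52 ± 0.19), and lowered the ETn elements ETnERV-int (−3.50 ± 0.05 and −3.38 ± 0.05) and MMETn-int (−4.32 ± 0.05 and −4.26 ± 0.05), L1MEi (−4.66 ± 0.06 and −4.18 ± 0.06), Kanga11a (−3.58 ± 0.12 and −3.65 ± 0.12) and RLTR9E (−1.69 ± 0.06 and −1.53 ± 0.06). RA changed 585 repeats in WT, 289 higher and 296 lower, and 542 in DKO, 274 higher and 268 lower. The interaction was called for 78, 33 positive and 45 negative, and for 44 with limma without trend. The deposited repeat values carry size factors of their own. With those of the gene table, RA raised 155 repeats and lowered 562 in WT, and raised 153 and lowered 470 in DKO. The genotype split after RA was 80 higher and 37 lower, and the interaction split was 42 positive and 29 negative. The median repeat then shifted by RA by −0.34 in WT and −0.24 in DKO. Under this scaling the RA effect on MERVL-int in DKO, 0.27 ± 0.06 as deposited, was 0.02 and not called (adjusted p = 0.839, over 22 alternatives 6.6e-05 to 0.839).

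In the authors' deposited comparisons 5361 genes in serum/LIF and 7057 after RA were called for genotype, of which 5055 and 6629 were also called here, all with the same sign. For the repeats the authors' tables called 121 and 127, of which 109 and 119 were called here with the same sign.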

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

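The tests of the 3 patterns weighed here were chosen after the result was seen, and the counts of other splits of the libraries were planned.

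The genotype effect differed between serum/LIF and RA, by the interaction test, in 4852 genes and 78 repeats. Interaction medians of the lists that passed were 1.30 for naive pluripotency, 0.50 for general pluripotency, 0.30 for p53 response and 0.13 for proliferation, and −1.50 for neural progenitors, −1.60 for neurons, −0.80 for neuronal targets of REST, −0.51 for trophoblast, −1.31 for the two-cell-like state, −0.58 for bivalent regulators, −1.08 for fibroblast markers and −0.47 for imprinted genes. With an estimated correlation 4 of these did not pass: proliferation (adjusted p = 0.123), neuronal targets of REST (0.152), trophoblast (0.264) and the two-cell-like state (0.0916). The two-cell-like median is also limited by low counts, since 9 of 22 genes had 0 reads in DKO in serum/LIF. The values in parentheses below are log2 interactions of single genes and repeats.

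Among pluripotency genes the interaction was called for Tfcp2l1 (1.90), Tet2 (1.35), Tbx3 (−0.67), Socs3 (−0.63), Pou5f1 (1.64), Utf1 (1.71), Nanog (1.36). It was also called for Klf2 (1.25), Dppa3 (1.95), Zfp42 (0.72), Esrrb (1.54). Formative and other ones were Etv5 (2.02), Otx2 (2.46), Pim2 (−1.37), Cdh2 (−1.41), Dnmt3a (0.36), Foxd3 (−1.87) and Tdh (1.30). Among neural genes it was called for Nes (−0.37), Sox1 (−2.17), Fabp7 (−5.18), Sox21 (−2.08) and Dbx1 (−4.51). Further ones were Sox3 (−2.92), Ina (−0.66), Nefm (−3.86), Nefl (−1.60), Tubb3 (−1.17), Gap43 (−1.93), Vgf (−0.38), Bex1 (−0.52) and Rest (0.49). Fibroblast, trophoblast, endoderm and mesoderm genes with a called interaction were Acta2 (−1.57), Tagln (−1.33), Col1a1 (−0.87), Col1a2 (−1.52), Col3a1 (−1.31). Epithelial and other ones were Krt8 (−2.21), Krt18 (−1.57), Krt19 (−1.41), Esx1 (−0.96), Col4a1 (−0.86), Col4a2 (−1.32), Kdr (−2.47), Meox1 (1.66), Bmp4 (1.63) and Gbx2 (−0.58).

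For genes of the RA response and Hox genes the values were Stra8 (1.73), Stra6 (−1.38), Crabp1 (−1.24), Crabp2 (0.26), Rarg (1.62), Cyp26a1 (0.39). Homeobox genes had Meis1 (−0.69), Hoxb2 (0.75), Hoxa3 (0.77), Hoxb8 (−1.27) and Hoxd3 (−1.96). Hoxd3 had 0 reads in serum/LIF in WT and in DKO, so its value only repeats the genotype effect after RA. For p53, proliferation, chromatin and imprinted genes they were Plk2 (0.65), Ccng1 (0.24), Mdm2 (0.24), Zmat3 (0.48), Bbc3 (0.63), Top2a (0.33). Chromatin and imprinted genes had Jarid2 (0.80), Cbx7 (−0.99), Gse1 (0.54), Peg10 (−1.09), Plagl1 (−1.75), Igf2r (−1.27), Dlk1 (−2.96) and Igf2 (−1.37). Y-linked genes with a called interaction were Usp9y (−2.93), Ddx3y (−0.52) and Uba1y (0.88). Genes chosen for the size of their change had Tex13b (−4.48), Npy (−4.29), Pcdh17 (−3.73), Vwa3b (2.16), Nlrp4a (4.10), Capn11 (1.75). Others were Grin2c (1.96), Usp26 (0.82), Cyp1a1 (1.90), Xist (2.31), Pramel39 (−4.75), Chrna9 (3.23). Next came Pirt (3.81), Accsl (3.61), Slc15a1 (3.33), Myo1g (3.29) and Vit (−4.46). Some of the values above rest on few reads. After RA, Pirt had 0 reads in WT and 8 in DKO (at least 2.63-fold). Chrna9 had 2 and 20 (9.88-fold, counting interval 2.40 to 87.2), and Otx2 had means of 2.54 and 13.5. Pramel39 had 6 reads in WT and 0 in DKO in serum/LIF. The sizes of these interactions depend on the 1 added before the log2 step. When each library was left out, some calls ended. Vwa3b was not called in 7 of 12, at worst without replicate 1 of WT after RA (adjusted p = 0.0704, over 19 alternatives 3.95e-07 to 0.245). Vgf was not called in 7 of 12, at worst without replicate 3 of DKO in serum/LIF (adjusted p = 0.144, over 19 alternatives 0.0303 to 0.144). Uba1y was not called in 6 of 12, at worst without replicate 3 of DKO after RA (adjusted p = 0.114, over 19 alternatives 0.00162 to 0.114). Hoxa3 was not called in 5 of 12, at worst without replicate 3 of WT in serum/LIF (adjusted p = 0.0832, over 19 alternatives 0.0049 to 0.111). Cyp26a1 was not called in 8 of 12, at worst without replicate 3 of WT in serum/LIF (adjusted p = 0.0789, over 19 alternatives 0.00337 to 0.122). Hoxd3 was not called with edgeR (adjusted p = 1.00, over 19 alternatives 1.51e-05 to 1.00). Pramel39 was not called with edgeR (adjusted p = 0.841, over 16 alternatives 7.07e-08 to 0.841). Otx2 was not called with pseudocount 0.5 (adjusted p = 0.0612, over 19 alternatives 3.57e-05 to 0.0612). Crabp2 was not called with limma without trend (adjusted p = 0.059, over 19 alternatives 0.00297 to 0.059).

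Among repeats the interaction was called for MERVL-int (−2.61), MT2_Mm (−1.83), IAPEz-int (0.25), IAPLTR3-int (1.86), MMVL30-int (−1.02), RLTR6_Mm (−0.86). Others were L1Md_T (0.50), GSAT_MM (−2.53), MMERGLN-int (0.36), L1M6B (−1.64), (ATAAG)n (−1.23), RLTR1B-int (−0.20), RLTR51B_Mm (1.27), L1MEi (0.48), L1ME4c (0.45) and (ATAGG)n (0.88). Leaving out libraries ended 2 of these calls. IAPEz-int was not called in 11 of 12, at worst without replicate 2 of WT after RA (adjusted p = 0.129, over 21 alternatives 0.000146 to 0.251). RLTR1B-int was not called in 8 of 12, at worst without replicate 2 of WT in serum/LIF (adjusted p = 0.113, over 21 alternatives 0.0106 to 0.424).

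Two-cell-like genes were lower in DKO after RA. The WT library rich in rRNA-class repeats does not account for this, since without it the list median was −4.09. A shift of reads between near-identical Zscan4 copies does not either: summed over 5 copies, counts were 84.6 in DKO and 3925 in WT, a log2 difference of −5.52 (SE 0.06). A lower two-cell-like state as an effect of genotype stays open as a hypothesis, beside the history of the clones, which was not tested.

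Y-linked genes were higher in DKO in serum/LIF. A loss of the Y chromosome in a share of the WT cells would raise them by 1 amount, but the rises of Eif2s3y and Uty, chosen after their values were seen as the highest and lowest of 5, differed by 2.76 (SE 0.13), which argues against it as the whole cause. Reads of the X-linked homologues do not account for the 6 called genes, since each rose by more than its own homologue, with a smallest difference of 0.27 (Uty, SE 0.10), and the largest log2 rise of a homologue was 0.14 (Usp9x, chosen after its value was seen). Genotype and the history of the clones stay open and were not tested.

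Pluripotency genes were higher and neural genes lower in DKO after RA. Undifferentiated cells left in the cultures were weighed at their full DKO serum/LIF levels, and levels changed by RA were not tested. The share of 2.60% that Pou5f1 would need was added to the WT level after RA. Of 63 genes that RA lowered at least 16-fold in WT, 19 lay more than 2 SD below the level needed (30.2%) and 10 as far above. At the median share of 1.95%, 12 lay below and 13 above. That share was the median over the same 63 genes, so a near-even split was set by the choice and tells nothing of a lean. The 12 and 13 show only that single genes departed from that share in both directions. With left-over cells at their full DKO serum/LIF levels, the Pou5f1 share argues against them as the whole cause. A single share of left-over cells would ask about the same of every gene. Single genes would need shares from −2.82% to 11.5%, and 7 of 63 were lower in DKO than in WT. Left-over cells as part of the cause, beside other changes, were not tested and stay open. Without the WT level, 3 of 63 (Tdgf1, Otx2 and Tdh, chosen after their values were seen) lay below (4.76%). With a 64-fold limit, which had been noted first, 3 of 16 did (18.8%). For neural progenitors, however, 2.60% would give −0.04, against a list median of −1.12. The 17 induced genes of the RA response list had a median of 0.0706, which argues against a weaker action of RA that lowered them as far. Their SD was 0.99, with 4 higher and 6 lower. The 95% interval of −0.37 to 0.37 came from resampling these genes, which are not independent replicates, and holds no spread between libraries. A milder weaker response stays open. Other genes that RA induced at least 4-fold, chosen on 1 WT library and compared with the other 2, had a median of −0.21. Other genes that RA lowered at least 4-fold, chosen in the same way, had medians of 0.19 to 0.24 over the choices of library. The SDs across genes were 1.25 to 1.26 for induced and 1.04 to 1.07 for lowered genes. Without the rRNA-rich library the neuron median was still −1.13, and an effect of genotype stays open as a hypothesis, beside the history of the clones.

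For the interaction 1 of 100 splits of the libraries, the real one, called as many genes and 1 of 100 as many repeats. The highest other counts were 2784 genes and 40 repeats, against 4852 and 78. Splits that mix WT and DKO put the genotype effect into the spread between libraries and so call fewer. They cannot decide whether chance gave the interaction counts. The other comparisons allow 10 splits, too few for a share under 0.05, and 1 split, the real one, gave the count in each. Real gene counts of 5230, 6727, 12695 and 12340 stood against 0 as the highest other, and repeat counts of 115, 129, 585 and 542 against 1, 0, 1 and 0.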

How the results depend on the processing

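The edgeR test, the gene table's size factors for repeats, lists without replicate 2 of WT after RA, and the processing alternatives of the overlaps were chosen after the result was seen. With a log2 fold change of 1 or more, fewer passed. Genes called were 1224 (DKO against WT in serum/LIF), 1293 (after RA), 6043 (RA in WT), 5291 (RA in DKO) and 1193 (interaction). Their splits into higher and lower were 659 and 565, 492 and 801, 3486 and 2557, 3051 and 2240, and 454 and 739, so the near-even split after RA leaned to lower. Repeats called were 11, 15, 176, 127 and 13. They split into 8 higher and 3 lower, 5 and 10, 85 and 91, 62 and 65, and 4 and 9. Shared calls were 376 (from 2246) between both genotype effects and 732 (from 3451) between genotype and RA, since the threshold removes smaller changes. The former were 100 higher and 276 lower, from 1176 and 1070, and the latter 502 and 230. limma without trend called 61 repeats in serum/LIF and 44 for the interaction, and the cause was not tested. With the gene table's size factors IAPEz-int turned to −0.16 (adjusted p = 0.0347, over 22 alternatives 0.000904 to 0.103) for RA in WT, a call that also ended without replicate 3 of WT in serum/LIF (adjusted p = 0.103) or after RA (0.0546). MMERGLN-int turned to −0.0453 (adjusted p = 0.479, over 22 alternatives 7.47e-07 to 0.479) for RA in DKO. The median repeat shifted by −0.34 for RA in WT and −0.24 in DKO. Leaving out each library gave 4401 to 5470, 5723 to 6841, 12228 to 12744, 11802 to 12365 and 4242 to 4778 genes. It gave 95 to 136, 529 to 590, 472 to 556 and 54 to 87 repeats for the comparisons after the first, and 1924 to 2216 and 2901 to 3550 shared calls. For repeats in serum/LIF it gave 72 to 117, with 72 without replicate 2 of WT and 73 without replicate 1 of DKO in serum/LIF, and the cause was not tested.

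Library numbers did not pair: residuals of like-numbered libraries correlated at −0.03 to 0.05 across genes over 18 pairs of libraries, and with the replicate block 5061, 6537, 12651, 12282 and 4662 genes and 105, 127, 582, 535 and 73 repeats were called. Of 110 list tests 57 passed, as did 57 with the replicate block, 47 with an estimated correlation and 57 without replicate 2 of WT after RA, where 2 were lost and 2 gained. Of the named genes' results, 122 lost and 41 gained a call over 12 left-out libraries, and 6647 did not change. Zscan4 genes had few reads in DKO, so their folds in serum/LIF are limited by counts. For the repeats, scaling on their own table is the same setting as TMM rescaling.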

Other observations

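Other gene families moved with genotype, grouped after the data were seen by the stem of their symbols, with 263 stems of at least 8 tested genes. At the preset correlation 11 stems passed camera in serum/LIF, 6 after RA and 13 in the interaction, and none of these passed with an estimated correlation. In serum/LIF, collagen genes (Col) were higher in DKO in 20 of 41 cases and lower in 6 (median log2 fold change 0.54, adjusted p = 9.68e-05; adjusted p = 0.336 with an estimated correlation), cadherins (Cdh) were higher in 11 of 18 and lower in 0 (0.94, 0.000292; 0.324 estimated), and protocadherins (Pcdh) were higher in 8 of 11 and lower in 0 (1.48, 9.68e-05; 0.237 estimated). In the interaction, 16 of 41 collagens were negative, 3 positive and 22 not called (adjusted p = 0.00443; 0.616 estimated). Of 18 cadherins 9 were negative and 0 positive (0.00197; 0.484 estimated), and of 11 protocadherins 6 and 0 (0.00443; 0.423 estimated).

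The Pramel family, whose members include transcripts of early embryos, was lower in DKO in 8 of 15 cases and higher in 0 in serum/LIF (median −1.57, adjusted p = 0.00268; 0.336 estimated) and in 15 of 15 after RA (−4.11, 1.06e-07; 0.372 estimated). Its members are similar in sequence, so the split of reads between them is uncertain. Interferon-induced guanylate-binding proteins (Gbp) were lower after RA in 9 of 10 cases and higher in 0 (median −2.14, adjusted p = 0.000717; 0.78 estimated). Ribosomal protein genes were lower after RA in 32 of 53 cases and higher in 1 for the large subunit (median −0.14, adjusted p = 0.00135; 0.856 estimated) and lower in 22 of 47 and higher in 3 for the small one (−0.14, 0.0289; 0.84 estimated). Annexins (Anxa) were higher after RA in 8 of 11 cases and lower in 0 (median 0.40, adjusted p = 0.0119; 0.575 estimated). By chromosome, the median genotype effect in serum/LIF lay between −0.04 and 0.03 on the autosomes and was 0.10 over 579 genes of the X chromosome, against 0.02 after RA.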
